A study of Zea mays with 303 samples.

How the data were processed

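Cells were isolated from dissected anthers of the maize inbred line W23, fixed in Farmer's solution (an ethanol and acetic acid fixative), digested with wall-degrading enzymes and sorted on a BioSorter or a Namocell Hana instrument, per the labels' protocols. Each of the 303 samples was 1 cell. RNA was turned into libraries with a modified CEL-Seq2 protocol, in which each transcript copy carries a unique molecular identifier (UMI) and barcoded cells are pooled before sequencing. The sample titles place the cells in 4 library pools with index numbers 6, 11, 28 and 29. What differed between the pools besides the index, such as the anthers or the sorter, was not given in the sources used here. All cells formed 1 group, so the pools were treated as technical batches, and no cell type was labelled.

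The authors deposited a table of UMI counts, whole numbers per annotated feature and cell, with no normalization. Reads had been aligned with HISAT2 to B73 RefGen_v4, per the submitters' processing notes. The software version, the annotation release, the UMI counter and any filter on cells were not given in the sources used here. The deposited counts covered 17140 features, and every feature had a UMI in at least 3 cells. Of these, 16854 were Zm00001d identifiers and 131 were GRMZM identifiers. None of either kind was matched in the gene table used here, which belongs to the assembly Zm-B73-REFERENCE-NAM-5.0, so those genes have no name in the text. The other 155 features carried a symbol, of which 144 were found in the gene table, and together they held 5.43% of all UMIs. No 2 cells had identical counts.

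Cells with at least 500 genes detected were retained, which left 257 cells and set aside 46. Counts were scaled to the median total, log-transformed and clustered with scanpy 1.11.5 on 2000 variable genes, 15 principal components and 15 neighbours, with the Leiden method at resolution 1 (igraph 0.11.9). Only a random 50% of the genes, drawn with a fixed seed and holding 8601 genes, entered the clustering. All genes of the fixed lists were kept out of it. The levels reported per cluster come from the 8539 genes that did not enter the clustering, and genes that did are named only as genes that define a cluster. An exception is the share of plastid-encoded UMIs per cell, which is given without the clustering genes as well. It sums the 12 plastid-encoded photosynthesis genes and 11 plastid gene expression genes of the lists described below. The features rps3 and ycf70 were in neither list and are left out of it. The contrast of clusters 2 and 6 gives values of psaC, rps16, rpl33 and ycf70, and the account of cluster 4 gives a level of SIP1-2. All of these entered the clustering. The nuclear photosynthesis level drawn per cell also includes PSBQ1, which entered the clustering, and the observations at the end give levels of MAD2 and LBD6, which entered it too. Clusters were numbered by size. No doublet caller was run, so wells or barcodes that held more than 1 cell were not removed.

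UMIs were summed per cluster and over all other retained cells and expressed as CPM, the count scaled to a total of 1000000. Fold changes are log2 ratios with 10 CPM added to both sides, which shrinks the folds of low genes. Intervals are exact 95% intervals (Poisson for CPM, Clopper-Pearson for shares) computed with scipy 1.17.1, and they cover counting error only. Each fold was also computed within every pool with at least 5 cells on both sides. The cells came from 1 group with no named plant or culture, so there were no replicates, no test between clusters was made and no p-value is given.

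The named genes were fixed by rule before the data were examined. For each cluster the rule took the 10 genes with the largest fold above and the 5 with the largest fold below the other cells. It drew on the 3059 genes with at least 50 UMIs, and the genes had to keep their direction in every pool compared. A gene named as higher also needed a UMI in at least 25% of the cluster's cells. Because most genes found this way had no name, the 5 symbol-bearing genes with the largest fold in each direction were added after the names had been seen. The fixed lists, 14 in number, covered meiocyte, tapetum, epidermis, endothecium and vascular markers, S and M phases of the cell cycle, cytoplasmic ribosomes, stress, cell wall, small RNA, lipid transfer, flavonoid and mitochondrial energy genes. They were matched by symbol only, since the gene table held no product descriptions. Of them, 7 matched no feature and the others matched 9 genes together. A further 9 lists were drawn up after the symbols had been seen: plastid-encoded photosynthesis, plastid-encoded gene expression, nuclear photosynthesis, aquaporin, cytoskeleton, ribosomal protein, chromatin, endoplasmic reticulum folding and mitochondrial genes. A list's level is the median log2 fold of its members with at least 20 UMIs, set beside its percentile among 10000 random lists matched on size and mean expression.

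The steps were tested on simulated data. In cells drawn from the mean profile of the retained cells with their real depths, 100 genes raised 4-fold and 100 raised 8-fold in 63 cells, drawn from the 3059 genes with at least 50 UMIs, gave median log2 folds of 1.62 and 2.66 where 1.72 and 2.72 were expected, since the raised genes also enlarge the total to which counts are scaled, and 1 cluster held all 63 cells. Cells drawn from a common profile, with no groups at all, were still divided into 9 clusters. These simulated cells varied by counting error only, with no difference between pools. When these were clustered on the other genes the adjusted Rand index between the partitions was 0.00547, where 1 is identity, and the best-matching clusters shared at most 15.7% of their cells. The 99.9th percentile of the log2 folds of genes outside the clustering reached 1.93 in such clusters. The number of clusters by itself is therefore no measure of structure.

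Alternatives covered the cells retained, the clustering settings, a ComBat correction for pool, the constant added, the weighting of cells and pools, the scaling, and the omission of each pool. Some further alternatives, among them other random sets of genes and the removal of features with equal counts, were chosen after seeing the data.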

Results

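Transcripts were counted in fixed single cells from early meiotic maize anthers, the pollen-forming organs at the stage when their central cells enter meiosis. The cells fell into 4 library pools, with 55 cells in pool 6, 78 in pool 11, 79 in pool 28 and 91 in pool 29. The whole set held 800166 UMIs. A cell had a median of 1780 UMIs, with a maximum of 9934, and a median of 1237 genes detected. The pools differed in depth, with medians of 2942, 2803, 1162 and 1746 UMIs for pools 6, 11, 28 and 29. Cells with barcodes 1 to 48 were deeper than those with barcodes 49 to 96 in every pool, by ratios of medians from 1.32 in pool 6 to 2.58 in pool 29. Thinned to 882 UMIs each, the cells with at least that many had a median of 682 genes.

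**Figure D1:**
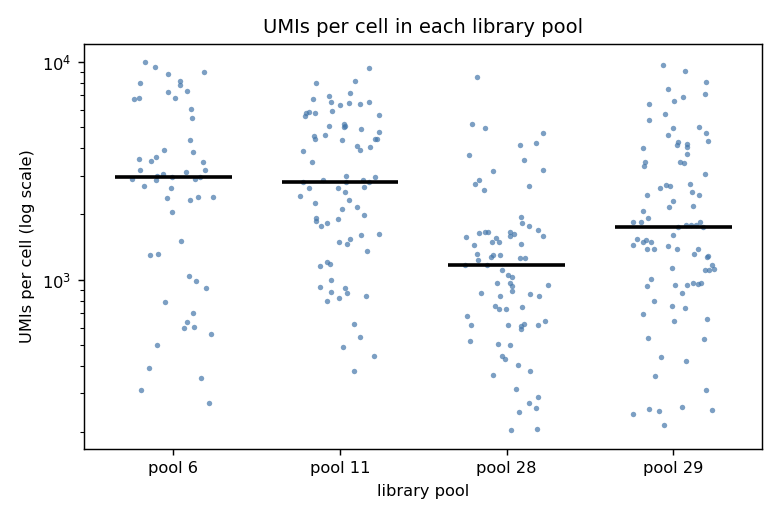
UMIs per cell on a log scale for each of the 4 library pools; each point is 1 cell and each line is the pool's median. The medians of pools 6 and 11 (2942 and 2803 UMIs) lie above those of pools 28 and 29 (1162 and 1746 UMIs).

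The first question was which kinds of cell the anther preparation held. The retained cells formed 9 clusters of 48, 33, 32, 31, 26, 25, 23, 20 and 19 cells, numbered in that order. Clusters 1, 3, 4, 5, 7 and 8 drew cells from all 4 pools. Cluster 4 held 16.7%, 8.57%, 16.7% and 8.86% of the cells of pools 6, 11, 28 and 29, and cluster 5 held 10.4%, 10.0%, 13.3% and 7.59%. Cluster 2 was mainly from pools 6 and 11, with 30 of its 33 cells. In this clustering cluster 6 came from pools 28 and 29 alone, with 15.0% (95% interval 7.10% to 26.6%) and 20.3% (12.0% to 30.8%) of their cells, and no cell of pools 6 and 11, which allows a share of up to 3.08%. After ComBat correction for pool, the matching cluster took 6.25% of pool 6 and 8.57% of pool 11. All 19 cells of cluster 9 came from pool 29, so cluster 9 may be a property of that pool and not a kind of cell. Clusters 2, 4, 5 and 6 were found again when the settings or the genes used were changed, with median overlaps of 90.9%, 100%, 96.2% and 89.3% of cells over 17 alternatives. With the 4 omissions of a pool included, the lowest overlaps were 61.5%, 95.5%, 60.0% and 66.7%. The median overlaps of clusters 1, 3, 7, 8 and 9 were 42.0%, 33.3%, 48.8%, 42.9% and 51.5%, so their borders depended on the settings.

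**Figure D2:**
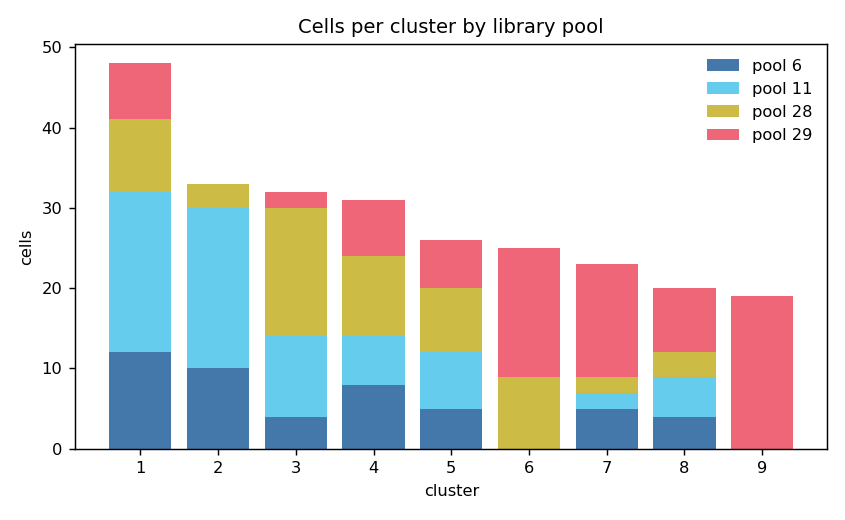
Number of cells in each of the 9 clusters, with bars divided by library pool. Clusters 1, 3, 4, 5, 7 and 8 hold cells of all 4 pools, cluster 6 holds cells of pools 28 and 29 alone, and all 19 cells of cluster 9 are from pool 29.

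Nuclear photosynthesis genes marked cluster 6. CAB1, which encodes a chlorophyll a/b-binding protein, reached 6456 CPM (5874 to 7080) in cluster 6 against 603 CPM in the other cells, a log2 fold of 3.40. RBCS, the small subunit of Rubisco, stood at 1918 against 215.6 CPM (log2 fold 3.10), and PSAH, a subunit of photosystem I, at 687 against 69.0 CPM (log2 fold 3.14). Within pools 28 and 29 the median log2 fold of these 3 genes was 3.76 and 3.35. RCA1, Rubisco activase, had 8 of its 11 UMIs there. CAB1, PSAH and RCA1 are the 3 detected members of the endothecium list fixed in advance. The endothecium is a wall layer of the anther whose cells carry chloroplasts. All 3 were higher, so cluster 6 is called endothecium-like. RCA1, with its 11 UMIs, lies below the limit of 20 UMIs for list members and adds little. All 3 genes are also in the nuclear photosynthesis list, so the name is a label and does not establish the kind of cell. No other cluster met the condition for a name, which cluster 2 missed for want of RCA1 alone. The 3 members of the nuclear photosynthesis list used were higher in cluster 6 with a median log2 fold of 3.14, at percentile 99.5 of random lists. C2, the chalcone synthase gene colorless2, was lower there, at 28.6 CPM against 827 CPM (log2 fold -4.44), a level carried mainly by cluster 5; within pools 28 and 29 the log2 folds were -2.11 and -4.53. The median log2 fold of all genes in cluster 6 was -0.44, and the values above are relative to all UMIs.

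Cluster 2 had the largest share of UMIs from plastid-encoded genes. How well the libraries captured plastid transcripts beside nuclear ones was not measured, so these shares need not be those of the transcripts. Genes of the plastid-encoded lists took a median of 7.79% of its cells' UMIs, against 4.19% in cluster 6 and 0.727% to 1.33% in the other clusters. This share includes genes that entered the clustering; without them it was 3.33%, against 1.39% in cluster 6 and 0.362% to 0.549% in the others. All 7 plastid-encoded photosynthesis genes used were higher, with a median log2 fold of 2.92 at percentile 100 of random lists. Among them psbB, a core antenna protein of photosystem II, stood at 2321 CPM (2086 to 2577) against 242.2 CPM (log2 fold 3.21), and ndhE, a subunit of the plastid NADH dehydrogenase-like complex, at 618 against 51.0 CPM (log2 fold 3.36). All 5 genes of plastid gene expression used were higher too, with a median log2 fold of 2.22, among them the RNA polymerase subunit rpoC2 at 9200 against 1386 CPM (log2 fold 2.72). Of the photosynthesis list 5 of 12 genes entered the clustering, and of the gene expression list 6 of 11. Cluster 2 was thus formed partly on plastid-encoded genes, so the levels and the percentile of the others are not independent of it. Nuclear photosynthesis genes had a median log2 fold of 1.04 in cluster 2 over all other cells, but within pools 6 and 11, where no cell of cluster 6 lay, CAB1 had log2 folds of 3.43 and 3.42 and RBCS of 4.82 and 4.73. PSAH had 26 UMIs in cluster 2 there and none in the other cells, so its fold is a lower bound. In those pools CAB1 stood at 1843 CPM (1630 to 2076) in 30 cells of cluster 2 and at 158.7 CPM in the other 88 cells. RCA1 had no UMI in cluster 2, which allows up to 24.3 CPM against 17.5 CPM elsewhere, so its direction cannot be read. With CAB1 and PSAH alone seen to be higher, the cluster keeps its number. That it has no name rests on RCA1 and does not show that its cells differ in kind from those of cluster 6.

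Set against each other over all pools, clusters 2 and 6 differed in both sets of genes, in a contrast that was almost wholly one between pools. All 7 plastid-encoded photosynthesis genes used were higher in cluster 2, with a median log2 fold of 1.44 over cluster 6. CAB1, RBCS and PSAH were lower, with log2 folds of -1.73, -1.36 and -1.80. Of the listed plastid-encoded genes that entered the clustering, psaC and rps16 were lower (-0.49 and -0.32) and the others higher. The intervals of psaC and of rpl33, which was higher at 0.26, included no difference. Outside the lists, rps3 and ycf70 differed little, at 10364 against 8804 CPM and 2124 against 1918 CPM. In pool 28, which held both, the levels of nuclear photosynthesis genes overlapped, at 5458 to 13492 CPM in 3 cells of cluster 2 and 3541 to 18172 CPM in 9 cells of cluster 6. A single feature, Zm00001d029056, was among the genes that define cluster 2 and alone took 87153 CPM there against 7323 CPM elsewhere. With this composition the median log2 fold of all genes in cluster 2 was -0.93, and -0.51 when the 20 most abundant genes were left out of the scaling. Thinned to equal depth, its cells had a median of 466.5 genes, against 623 in cluster 6. Values below 0 in cluster 2, such as the aquaporin list at -2.80, are to be read against that shift.

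**Figure D3:**
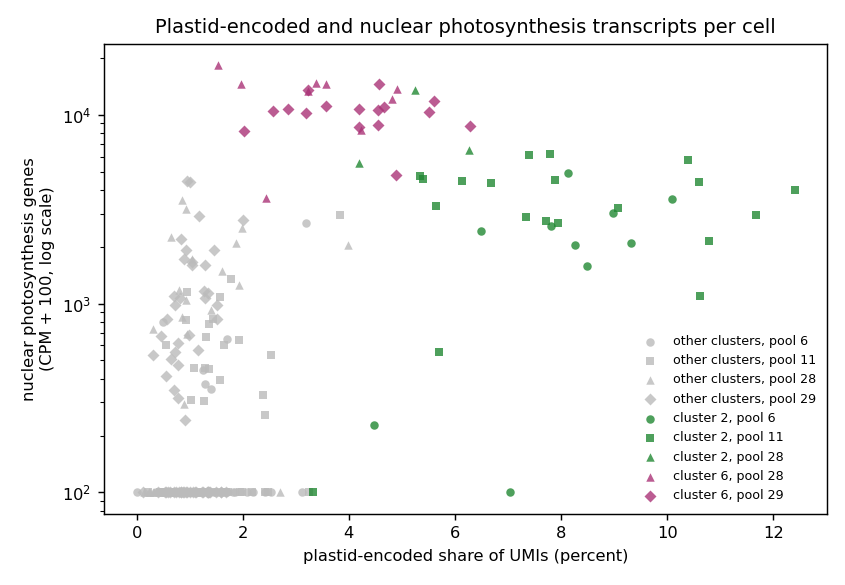
Plastid-encoded share of UMIs (x axis, percent, genes that entered the clustering included) against the level of nuclear photosynthesis genes (y axis, CPM with 100 added, log scale) for the retained cells; colour gives cluster 2, cluster 6 or other clusters, and the symbol gives the pool. Cells of cluster 6 lie at high nuclear levels with a median plastid-encoded share of 4.19%, and cells of cluster 2 extend to the largest shares, with a median of 7.79%.

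Cluster 5 was set apart by the flavonoid gene C2. C2, which catalyses the entry step of flavonoid synthesis, reached 5384 CPM (4913 to 5888) against 157.9 CPM in the other cells, a log2 fold of 5.01, with 480 of its 589 UMIs in these 26 cells. The fold held in each pool, from 4.00 in pool 29 to 5.97 in pool 6. The aquaporin genes NIP1-1 and PIP1-3 had log2 folds of 2.91 and 1.54, the vacuolar aquaporin TIP1-1 one of 1.08, and the superoxide dismutase gene SODCC.2 one of 1.68, all higher in all 4 pools. The other 2 aquaporins used, PIP2-1 and PIP2-2, were not higher, with log2 folds of -0.42 and -0.17. The list had a median of 1.08 in cluster 5, against 1.38 in cluster 9 and 1.00 in cluster 8 over all pools. It turned to -0.17 in cluster 5 when all members outside the clustering with a UMI were used. That setting added NIP3-1 and PIP2-6, each with fewer than 20 UMIs. Within pools the median of the list was 0.79 to 1.26 in cluster 5, against 0.47 in cluster 9 and 0.55 and 0.54 in cluster 8. A UMI of C2 was seen in 84.6% of the cells of cluster 5 and in 8.00% of those of cluster 6, at median depths of 2746 and 1783 UMIs. RBCS and PSAH had no UMI in cluster 5, which limits them to 41.4 CPM each. CR4, the receptor kinase crinkly4 and the single matched gene of the epidermis list, had 5 of its 12 UMIs in cluster 5, too few and too alone to name it.

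Cluster 4 showed high transcript levels of GAPC3 and of mitochondrial carrier genes, and few plastid transcripts. GAPC3, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, stood at 1703 CPM (1481 to 1949) against 178.4 CPM (log2 fold 3.18), while GAPC2, of the same family, was lower, at 443.9 against 675.7 CPM (log2 fold -0.60). The mitochondrial ADP/ATP carrier genes ANT2 and ANT1 had log2 folds of 1.76 and 1.25, and the ribosomal protein genes RPS21 and RPL17 of 1.44 and 1.16. GAPC3 and these 4 genes were higher in each of the 4 pools, but the ribosomal protein gene RPL29 was lower, with a log2 fold of -2.27. RPL29 was highest in cluster 6, at 257.7 CPM, whereas RPS21 and RPL17 were highest in cluster 4. Which ribosomes these proteins belong to was not given in the gene table, so the 3 genes need not form 1 set. The aquaporin list had a median log2 fold of -2.77 and the plastid-encoded photosynthesis list one of -2.72, while C2 stood at 40.4 against 891 CPM (log2 fold -4.16). The aquaporin median left out SIP1-2, which entered the clustering and went the other way. SIP1-2 stood at 1630 CPM in cluster 4 and at 818.8 CPM or less in every other cluster. The other cells of the plastid-encoded fold include clusters 2 and 6, and their C2 level was carried mainly by cluster 5. C2 was about as low in clusters 2 and 6, at 46.0 and 28.6 CPM. All 10 genes that the rule selected as higher in cluster 4 lacked a name. The one with the largest fold, Zm00001d011630, stood at 1340 against 44.2 CPM (log2 fold 4.64). Among genes that define cluster 4 were EZ1, a Polycomb histone methyltransferase, and BIPE2, an endoplasmic reticulum chaperone, with log2 folds of 2.25 and 2.24.

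The other 5 clusters were less stable. Cluster 9 was high in aquaporins, with TIP1-1 at 2065 against 394 CPM (log2 fold 2.36) and PIP2-2 at 829 against 190 CPM (log2 fold 2.07). Against the other cells of pool 29 alone these folds were 1.80 and 1.05, and the median of the 5 aquaporins fell from 1.38 to 0.47. In cluster 8 CAB1 stood at 46.1 against 1191 CPM (log2 fold -4.42), and RBCS and PSAH had no UMI. The CAB1 level of the other cells was carried mainly by clusters 6 and 2 (6456 and 1933 CPM). Clusters 1, 4, 5 and 7 were about as low in CAB1, at 52.9, 96.8, 112.2 and 104.5 CPM. NIP1-1 had a log2 fold of 2.04 in cluster 8, but of 2.42 within pool 11 and 0.54 within pool 29. Cluster 7 was highest for SGS3, a factor in the making of small interfering RNAs, at 706 CPM (465 to 1026) against 387 CPM, and was defined among others by PPDK2, pyruvate orthophosphate dikinase, with a log2 fold of 2.76. Cluster 3 was defined in part by the DNA-binding protein gene HMGIY2 (log2 fold 1.78) and had a higher level of the tubulin gene TUBA1 (log2 fold 0.55). Cluster 1, the largest, had low levels of nuclear photosynthesis transcripts, with CAB1 at 52.9 against 1311 CPM (log2 fold -4.39) and no UMI of RBCS or PSAH. Low CAB1 was not particular to it, as the levels of clusters 4, 5, 7 and 8 given above show. The aquaporin genes PIP2-1 and PIP2-2 had log2 folds of 0.45 and 0.52 in cluster 1, and their intervals included no difference. Simulated cells without any groups gave clusters with log2 folds that reached 1.93 at the upper percentile given with the methods, so folds under that value are by themselves weak evidence of separate kinds of cell, in these 5 clusters and in clusters 4 and 5 alike. That percentile was taken over genes of all levels from 50 UMIs up, and none was computed for well-counted genes alone. The simulation held no difference between pools and no spread beyond counting error. A fold above 1.93 is therefore not thereby shown to mark a kind of cell.

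**Figure D4:**
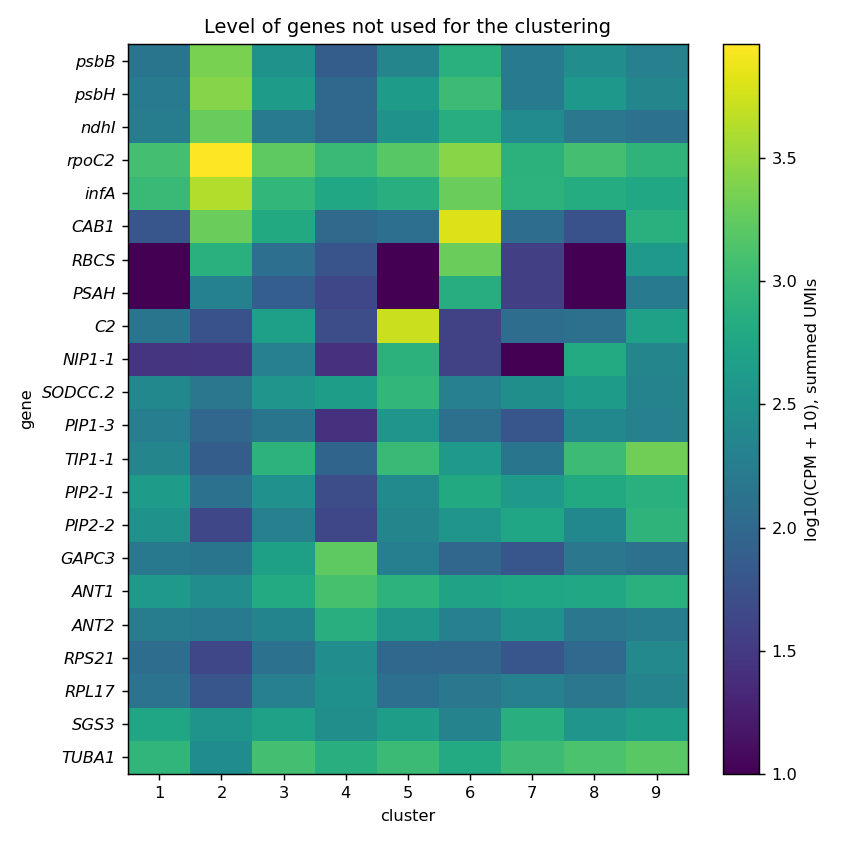
Levels of 22 symbol-bearing genes that did not enter the clustering, as log10 of CPM with 10 added, in the 9 clusters; rows are genes, columns are clusters and colour gives the level. CAB1 is at 6456 CPM in cluster 6, C2 at 5384 CPM in cluster 5 and GAPC3 at 1703 CPM in cluster 4.

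Cell identities could be read from few of the lists. The meiocyte list matched RAD51B alone, with 6 UMIs, and the S phase list matched PCNA alone, with 5 UMIs. The tapetum, vascular, M phase, cytoplasmic ribosome, stress, cell wall and lipid transfer lists matched no feature by name, which says nothing about whether their genes were expressed. The mitochondrial energy list rested on ANT1, the small RNA list on SGS3 and the flavonoid list on C2. Of the lists drawn up later, mitochondrial genes had their highest median in cluster 4 (log2 fold 1.25), with 2 of 3 members higher and EFTS at -0.40. The ribosomal protein list, whose members need not form 1 set, had a median of 1.16 in cluster 4, with 2 of 3 members higher (percentile 94.5). In cluster 9 its median was 1.00, with all 3 higher (percentile 98.6). Cytoskeleton genes had their highest median in cluster 9 (0.93). Genes of endoplasmic reticulum folding reached 0.74 in cluster 9, and the chromatin list kept 1 usable gene, with values from -1.16 to 0.81.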

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

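The tests of depth on the 21PHAS features, the 2 tests of a whole cause for cluster 2, the shares of genes outside the clustering in pool 28, and the nuclear ratios divided by those of total UMIs, were chosen only after the results had been seen. The test in pool 28 was written beforehand, but its code first held a further condition on the medians that left it undecided; that condition, absent from the written prediction, was removed after the result had been seen. The design has 1 group, so no biological explanation was tested.

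Cells with fewer than 500 genes were in no cluster, yet held 640 UMIs of plastid-encoded genes, 3.11% of their 20607 UMIs against 2.77% in the retained cells. The median share of a left-out cell was 1.38%, and 3 cells of pool 11 with shares of 9.36%, 11.2% and 15.8% weighed heavily in the total. Of these 46 cells, 6 had a share at or above the lowest of cluster 2 (3.33%). They are signal in data that the comparisons left out.

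Nuclear photosynthesis genes were high in clusters 2 and 6, which drew on different pools, and a difference between library pools may divide 1 kind of cell into these clusters. Pool 28 held cells of both: the shares of plastid-encoded UMIs were 4.18% to 6.26% in 3 cells of cluster 2 and 1.53% to 4.91% in 9 cells of cluster 6. These ranges overlap, as such a split would predict, and so did those of genes outside the clustering (1.64% to 2.38% and 0.454% to 2.33%), but with 3 cells the test decides little. With clusters from all genes, 0% of pool 28 was in cluster 2, so the test then had no cells of it, and after ComBat correction 8.57% of pool 11 was in the cluster that matched cluster 6. A difference in anthers or stage between the pools stays open and untested.

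Plastid-encoded genes were high in cluster 2, and a loss of nuclear transcripts might raise their share. UMIs per cell of symbol-bearing nuclear genes outside photosynthesis were lower there than in the other cells of the pool, by ratios of medians of 0.789 in pool 6 and 0.897 in pool 11, which lie between the bounds set beforehand and leave a contribution open; divided by the ratios of total UMIs they were 0.400 and 0.560, below the bound of 0.67 set for UMIs per cell, but such a quotient also falls when other transcripts take a larger part of the total. As the whole cause it is argued against, since plastid-encoded genes outside the clustering had 9.56 times as many UMIs per cell in pool 11 and 9.67 times in pool 6, ratios that include a gap in median total UMIs (4475.5 against 2796.5 in pool 11 and 5815 against 2952 in pool 6) but exceed it. These ratios are not independent of the clustering, since cluster 2 was formed partly on plastid-encoded genes. Free plastid RNA in pools 6 and 11 also stays open as a contribution: the share in cells outside cluster 2 there was 1.39 times that in cells outside clusters 2 and 6 of the other pools, again between the bounds. Spread evenly over the wells it could not be the whole cause, because the median log2 fold over other wells of the same pool was 2.60 in pool 11 and 2.86 in pool 6, but cluster 2 was formed partly on plastid-encoded genes and an uneven spread between wells stays open.

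UMIs of the 21PHAS features, loci named for phased 21-nucleotide small RNAs, lay almost entirely in pools 6 and 11. These pools held 35 of the 36 UMIs, or 97.2% (85.5% to 99.93%), against 57.3% of all UMIs. Without 2 of the 3 cells with most of them, both from pool 11 and cluster 8, the share was 93.3% (68.1% to 99.83%) of 15 UMIs. UMIs of the same cell are not independent, and counted by cells the share was 92.3% (64.0% to 99.8%) of 13 cells, or 90.0% (55.5% to 99.75%) of 10 without the 3 cells, against 56.6% of all UMIs. This last interval includes the share of UMIs, while the others lie above it. Leaving the 3 cells out of a count by cells also makes that count smaller. With so few cells a difference in depth between the pools stays open, as do other differences between them.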

How the results depend on the processing

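The ComBat clusters for gene lists were chosen after seeing the data. Depth limited which genes could be read: low genes rested on a few UMIs, and PIP2-1 and PIP2-2 in cluster 1 could not be told from no difference. The number of clusters ran from 6 to 12 over 21 alternatives. Of the list levels, 1153 values stayed within their members' interval, 43 moved and 1 changed sign. Of the gene folds, 1372 stayed, 79 moved and 3 changed sign. A change of sign was counted only where a list lay in the outer percentiles of random lists or a gene's interval excluded no difference. Others were counted as stayed or moved. For nuclear photosynthesis in clusters 1, 5 and 8 the members' interval reached 9 log2 units to either side, so staying within it shows little. Leaving out pool 29 gave no value for cluster 9, which has no cell elsewhere.

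The median UMIs per cell was 2363 with at least 500 genes detected, 3051.5 with at least 1000, and 1543 to 2403.5 with pools left out in turn. Genes detected per cell were 1439 and 1845 under the same limits, 682 after thinning, and 1086 to 1446.5 with pools left out; fewer or deeper cells make up these values. With ComBat, cluster 6 took 8.57% of pool 11 and cluster 2 took 15.7%; with clusters from all genes, cluster 2 took 0% of pool 28.

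In cluster 2, plastid-encoded photosynthesis genes had a median log2 fold of 3.40 when scaled without the 20 most abundant genes and 2.17 with ComBat clusters; plastid gene expression had 2.70 and 1.92, and 2.01 to 2.34 with pools left out. Nuclear photosynthesis in cluster 2 rose to 4.21 with equal pool weights, set by PSAH with no UMI in the other cells of pools 6 and 11, and was 1.52 with that scaling and 0.46 to 2.18 with pools left out. In cluster 6 it was 3.50 as a mean over cells, 3.57 with equal pool weights, and 2.86 to 3.54 with pools left out.

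Among the changes of sign counted, aquaporins in cluster 5 turned to -0.17 with all members outside the clustering. C2 in cluster 9 turned to 0.054 with equal pool weights. TIP1-1 in cluster 3 turned to -0.81 with clusters from all genes and ran from -0.28 to 1.54 as pools were left out. Changes not counted included nuclear photosynthesis in cluster 9, at 0.085 over all pools and -0.90 with pool 29 alone. The cause was not tested.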

Other observations

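Few 21PHAS transcripts were seen, and most were in 3 cells. The 6 features of this kind had 36 UMIs in 13 cells, and 3 cells held 16, 5 and 5 of them. In the first cell 12 UMIs came from 21PHAS_NO350. A pair of genes below the limit for naming, chosen after their values were seen, were concentrated in clusters with few named genes. MAD2, a spindle checkpoint gene, stood at 149.8 CPM in cluster 1 and at 23.1 CPM or less in every other cluster, with 23 UMIs in the retained cells. LBD6, a gene of the LOB-domain family of transcription factors, stood at 276.9 CPM in cluster 8 and at 33.7 CPM or less elsewhere, with 20 UMIs in the retained cells. Both entered the clustering, so these levels are not independent of it.

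Some features had nearly the same count in every cell. In 34 pairs, made up of 61 features, the counts were equal in at least 90% of the cells with a UMI of either, with a median of 96.0%. Molecules assigned at random to either member would have been equal in a median of 45.8% of cells. Values of such features are uncertain, since reads counted at both members cannot be told from separate transcripts here.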
